A study of Mus musculus with 4 samples.

How the data were processed

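Single-cell RNA of 4 mouse libraries was counted by UMI: TBLC (1 library), control TBL-blastoids (2 libraries) and H2O2 TBL-blastoids (1 library). The labels give 1500, 2000, 2000 and 4000 loaded cells. The kit is given as 10x Chromium 3', but barcodes were 20 characters long in the TBLC and control lists and 16 in the H2O2 list. Whether the H2O2 library was made in the same way as the others is therefore not established. The authors deposited raw UMI counts per gene and barcode with no normalization. Per the file headers the TBLC and control count matrices were written by PISA and the H2O2 count matrix by Cell Ranger 7.0.0, while the submitters' processing notes name Cell Ranger 3.0.2, STAR, Seurat 4.3.0 and the mm10 build. Whether intron reads were counted is not given in the sources used here. The matrices held 1532, 2904, 2361 and 4824 barcodes and 79.9, 129.1, 94.0 and 85.2 M UMIs. The barcode list of control replicate 2 named 2090 cells while its matrix had 2361 columns, so cells were taken as matrix columns and the barcode lists were not used. The comparisons used the 25724 genes shared by the PISA and Cell Ranger files, of which 43 were joined by symbol, and positions came from GENCODE vM21.

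Cells with at least 1000 genes, at least 2000 UMIs and at most 20% mitochondrial UMIs were kept, and Scrublet doublets were removed, in scanpy 1.11.5. The caller marked very few doublets (1, 57, 16 and 3 cells), so doublets may remain among the kept cells. This left 1502, 2846, 2344 and 4818 cells. The 4 libraries were clustered together without batch correction (counts scaled to 10000 per cell, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2). A marker was raised in a cluster at 20 CPM or more and at least 2-fold over the median of the clusters counted by the same program, after a pseudocount of 10 CPM. A cluster took the class with the most raised markers, if these were at least 3 and more than for any other class. It stayed unnamed where another class had more markers among its 10 most raised genes, or where its median UMI count was under 0.333 of its library's and none of its class markers was among those 10. Taking the median over clusters of the same counting program was chosen after the file headers were seen. Shares carry exact Clopper-Pearson intervals at 95%, and shares of 0 carry the limit that 3 counts allow. For the 2-cell-like share each cell was thinned to 5000 UMIs.

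UMIs were summed per library, or per library and class with at least 20 cells, and compared with TMM scaling in edgeR 4.0.16 (quasi-likelihood test, Benjamini-Hochberg adjustment) in R 4.3.3. Libraries were the replicates: the whole-library fits held all 4 and the class fits the 3 TBL-blastoid libraries, and the 1 residual degree of freedom came from the 2 controls. The prior degrees of freedom were infinite in the main whole-library fits, so their p-values rest on a spread pooled over genes. No p-value holds variation between H2O2 libraries or between TBLC libraries. A gene changed when the adjusted p was under 0.05 and the log2 fold change at least 1 in size. The 24 gene lists and 13 marker lists were written before the data were examined, as were the comparisons and the rule for naming genes. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The rule allowed any list member, with preference to the 4 members of highest mean CPM among those that passed. It also named the 10 genes with the largest rise and the 10 with the largest fall (5 within a class) among those with a mean of at least 50 CPM in 1 of the groups and a change of at least 2-fold in the same direction against each control. Genes with 0 counts in a group carry a lower bound from 3 counts.

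On simulated data with the real depths, 50.7%, 52.2%, 55.2%, 32.8% and 43.3% of 2-fold changes were recovered in the comparisons of control with TBLC, of whole libraries, of EPI-like, PrE-like and TE-like cells. Of 4-fold changes 83.6% were recovered in PrE-like cells and 100% elsewhere, and at most 6 unchanged genes were called. The simulation drew all libraries from 1 profile with the spread of the 2 controls. The single libraries thus had no library or counting-program difference of their own, so the few false calls say nothing of such differences. The 2 controls differed by more than counting error (chi-square per degree of freedom 51.8 over 17453 genes). Alternatives planned were DESeq2 1.42.0, RLE size factors, no filter on low counts, doublets kept, at least 2000 genes per cell, Leiden resolutions 0.5 and 2, each library clustered by itself, thinned sums, fibroblast-like cells left out, ribosomal and mitochondrial genes left out, only the libraries of the 2 groups, and leaving out each control. Without a control the log2 difference was taken from CPM with 0.5 added and not from the fitted model. Chosen after the data were seen were the EPI-like comparison of control with TBLC, genes under 20 kb that overlap no other gene, the interaction of class and treatment, removal of the 5% of cells with the highest doublet scores and removal of clusters with a median UMI count under 0.5 of their library's.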

Results

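TBLCs are totipotent-like mouse cells that were obtained from induced pluripotent stem cells with an inhibitor of the spliceosome, and TBL-blastoids are structures resembling blastocysts that were grown from TBLCs. The 4 single-cell RNA libraries addressed which lineages of the blastocyst the TBL-blastoids held and how their cells differed from TBLCs. They also addressed what differed in TBL-blastoids grown from TBLCs that had been exposed to 1 mM H2O2 for 1 h and kept for 24 h in fresh medium, a treatment meant to bring about senescence. The deposited matrices were deep: the medians per cell were 46468 UMIs for TBLC, 38958 and 35703 for the control TBL-blastoids and 16467 for the H2O2 TBL-blastoids. Libraries and not cells were the replicates: the controls had n = 2, TBLC and H2O2 had n = 1, and each single library was assumed to vary like the 2 controls. The H2O2 matrix was written by another counting program than the other 3, and its barcodes were of another length. For the genes that differed within a class between H2O2 and control, the program and the treatment therefore cannot be told apart. A difference in how the libraries were made cannot be told apart from them either, and it may bear on shares and depth too.

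Control TBL-blastoids held cells with markers of all 3 blastocyst lineages, which are the epiblast (EPI), the primitive endoderm (PrE) and the trophectoderm (TE). PrE-like cells made up 62.6% of the kept cells of control replicate 1 (exact Clopper-Pearson 95% interval 60.8 to 64.4) and 59.9% of replicate 2 (57.9 to 61.9), a mean of 61.3% ± 1.87 (SD, n = 2). They formed 5 clusters and carried Gata6 and Gata4, transcription factors of the primitive endoderm, at 125 and 131 CPM (UMI counts scaled by the total of the class) in replicate 1 and at 198 and 152 CPM in replicate 2, and Cubn, an endocytic receptor of the visceral endoderm, at 147 and 217 CPM. EPI-like cells made up 23.0% ± 0.531 (SD, n = 2), with Pou5f1, a transcription factor of pluripotent cells, at 812 and 851 CPM. TE-like cells made up 15.6% ± 1.34 (SD, n = 2), with the keratin gene Krt8 at 1072 and 974 CPM and Gata2, a transcription factor of the trophoblast, at 444 and 547 CPM.

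H2O2 TBL-blastoids held few PrE-like cells: 82 of 4818, or 1.70% (1.36 to 2.11), against 62.6% and 59.9% in the controls. The 82 cells carried Gata6 at 176, Gata4 at 166 and Cubn at 571 CPM, and 80 of them formed 1 cluster of that library alone. EPI-like cells made up 33.9% (32.5 to 35.2), above both controls, but with Pou5f1 at 135 CPM. Shares of a library add up to the whole, so shares of other classes depend on how few PrE-like cells it held. TE-like cells made up 22.1% (20.9 to 23.3), with Krt8 at 1136, Krt18 at 2019 and Gata2 at 56.3 CPM, and with Cdx2, an early trophectoderm transcription factor, at 1.79 CPM against 30.8 and 29.3 CPM in control TE-like cells. Another 42.2% (40.8 to 43.6) fell into 2 clusters that met the naming rule of no class, while every control and TBLC cell lay in a named cluster. H2O2 clusters were named against the median of few H2O2 clusters, with these 2 in it. The unnamed shares of H2O2 and of the other libraries therefore cannot be compared. These 2 clusters carried Krt18 at 484 and 410 CPM, between EPI-like and TE-like cells of the same library, Pou5f1 at 100 and 89.8 CPM, and Zic2, a transcription factor of the later epiblast, at 62.7 and 79.1 CPM. At a Leiden resolution of 0.5 instead of 1, no H2O2 cell was left unnamed and the TE-like share was 57.4%, while the PrE-like share was again 1.70%. The clusters of each class differed between libraries, since EPI-like H2O2, control and TBLC cells lay in separate clusters, so a cluster of 1 library may reflect that library as well as its cells, and the intervals cover counting error only.

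**Figure D1:**
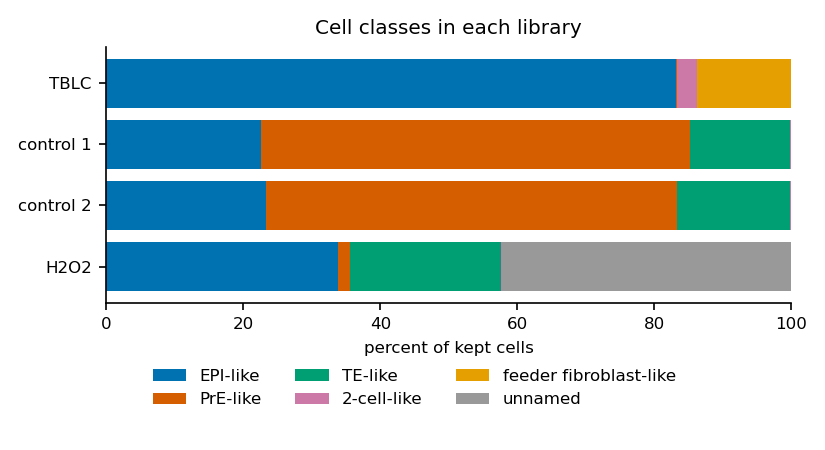
Percent of kept cells (horizontal axis) in each cell class (colours) for the 4 libraries (bars, 1 library each, no error bars). PrE-like cells fill 62.6% and 59.9% of the 2 control bars and 1.70% of the H2O2 bar, where 42.2% of the cells were unnamed. Clusters were named against clusters of the same counting program, so unnamed shares cannot be compared between H2O2 and the other libraries.

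In the TBLC library 83.2% of cells were EPI-like (81.2 to 85.1), 13.8% were fibroblast-like (12.1 to 15.6) and 2.86% were 2-cell-like (2.08 to 3.84). PrE-like cells numbered 2 of 1502, and TE-like cells 0 of 1502, which allows a share of up to 0.200%. The fibroblast-like cells carried the collagens Col1a1 and Col3a1 at 2268 and 1801 CPM and were named after the irradiated embryonic fibroblasts on which TBLCs were grown, and no control TBL-blastoid cell and 2 H2O2 cells were of this class. The 2-cell-like cluster held 43 TBLC, 5 and 4 control and 6 H2O2 cells and carried Zscan4c, a gene of a burst of expression in the 2-cell embryo, at 824 CPM.

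With each cell thinned to 5000 UMIs, at least 2 UMIs over the 2-cell-like markers were found in 4.46% of TBLC cells (67 of 1502, 3.47 to 5.63), in 0.246% and 0.384% of the control cells (mean 0.315 ± 0.098, SD, n = 2) and in 0.376% of H2O2 cells (0.223 to 0.593). As a background, 0 of 1781 and 0 of 1405 control PrE-like cells reached this count, which allows shares of up to 0.168% and 0.214%, at median depths of 34197 and 29708 UMIs before thinning. Within TBLC the share was 95.3% in the 2-cell-like cluster, 4.83% in fibroblast-like cells (10 of 207, 2.341 to 8.705) and 1.28% in EPI-like cells. The median depths were 34822, 31748 and 49910.5 UMIs. Neither the share in all TBLC cells nor that in TBLC EPI-like cells was above that of fibroblast-like cells. Whether fibroblast-like cells are free of all these markers was not tested, and 41 of the 67 TBLC cells lay in the 2-cell-like cluster. The 2-cell-like cluster was named by the same markers.

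**Figure D2:**
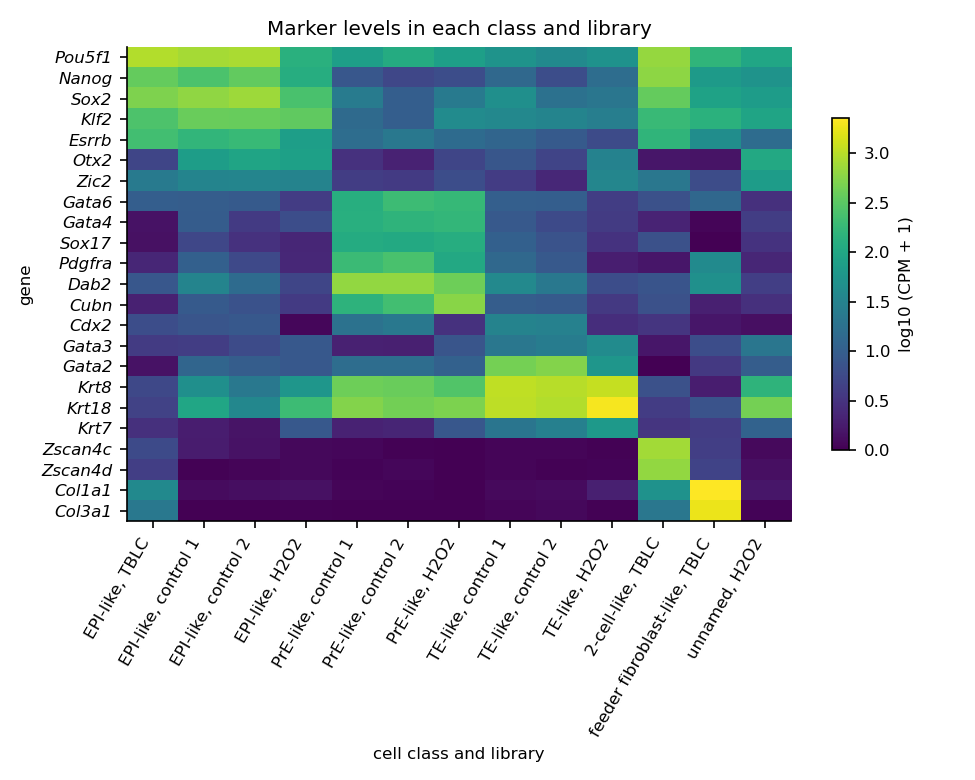
Level of marker genes as log10 of CPM plus 1 (colour) for each gene (vertical axis) in each cell class of each library (horizontal axis, 1 value per class and library). Gata6 stood at 125 and 198 CPM in control PrE-like cells and at 176 CPM in H2O2 PrE-like cells, while Cdx2 stood at 1.79 CPM in H2O2 TE-like cells.

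CPM given beside a tested difference are scaled by TMM factors as well, so they differ from the levels of the same gene given above. From TBLC to control TBL-blastoids, genes of the primitive endoderm and trophectoderm rose together with epithelial and glycolytic genes. All 16 PrE-like markers rose (median log2 fold change 5.37, limma's camera test adjusted p = 9.37e-14, and adjusted p = 0.441 with an estimated correlation). These included Sox17, a transcription factor of the endoderm (log2 fold change 6.64 ± 0.18, SE), and the basement membrane collagen Col4a2 (5.57 ± 0.20). Among the genes that rose most were Ttr, the thyroid hormone carrier transthyretin (11.97, 0.06 CPM in TBLC, 295 and 215 CPM in the controls), and the carbonic anhydrase gene Car4 (11.22). Of 18 TE-like markers 12 rose and none fell (median 2.07, adjusted p = 6.3e-06, and adjusted p = 0.484 with an estimated correlation). An example was Krt18 (7.02 ± 0.25) and Gata2 (7.27 ± 0.18). Among 20 genes of epithelial polarity and fluid transport, which serve the filling of the blastocyst cavity, 14 rose, 2 fell and 4 did not pass (median 2.70, adjusted p = 1.47e-05, and adjusted p = 0.561 with an estimated correlation), where the tight junction gene Cldn6 was at 7.37 ± 0.22. Of 27 glycolysis and hypoxia genes 17 rose, 1 fell and 9 did not pass (median 1.70, adjusted p = 4.21e-06, and adjusted p = 0.561 with an estimated correlation). They included the glucose-burning enzymes Ldha (2.13 ± 0.25, edgeR quasi-likelihood test, adjusted p = 3.6e-17) and Pgk1 (1.96 ± 0.25). Of 23 imprinted genes, 10 rose, 4 fell and 9 did not pass (median 0.61, adjusted p = 0.0289, and adjusted p = 0.58 with an estimated correlation), the noncoding RNA H19 by 6.85 ± 0.48. The unfolded protein and integrated stress response list had 5 of 22 members that rose and none that fell (median 0.66, adjusted p = 0.000381, and adjusted p = 0.561 with an estimated correlation). An example was Herpud1, a gene of protein degradation at the endoplasmic reticulum (2.31 ± 0.12).

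Genes of the 2-cell embryo, of germ cells and of feeder fibroblasts fell from TBLC to control TBL-blastoids. Of 20 tested 2-cell-like markers 17 fell and none rose (median -3.20, adjusted p = 6.91e-07, and adjusted p = 0.441 with an estimated correlation). These included Zscan4d (-3.57 ± 0.16). Of 8 germ cell-like markers 7 fell and 1 rose (median -1.99, adjusted p = 0.0013, and adjusted p = 0.484 with an estimated correlation), where Dazl, an RNA-binding protein of germ cells, was at -6.84 ± 0.13. Of 17 naive pluripotency genes, which keep the unrestricted early epiblast state, 7 fell, 2 rose and 8 did not pass (median -0.95, adjusted p = 0.00298, and adjusted p = 0.586 with an estimated correlation). An example was Nanog (-1.69 ± 0.12). Of 25 p53 targets 8 fell and none rose (median -0.67, adjusted p = 1.19e-05, and adjusted p = 0.561 with an estimated correlation). These included Perp (-1.59 ± 0.10) and Aen (-1.33 ± 0.11), both genes of apoptosis. Of 21 inflammatory and interferon genes 14 fell, 2 rose and 5 did not pass (median -3.03, adjusted p = 1.92e-06, and adjusted p = 0.561 with an estimated correlation). These included Isg15, a ubiquitin-like protein of the interferon response (-9.98 ± 0.16), and Ifitm3, a membrane protein against viral entry (-3.81 ± 0.18). Of 22 genes that rise in senescence 12 fell and 1 rose (median -1.14, adjusted p = 0.000174, and adjusted p = 0.561 with an estimated correlation). These included the secreted factors Ccl2 (-8.79 ± 0.15) and Igfbp7 (-7.82 ± 0.14). All 15 fibroblast markers fell with them (median -6.42, adjusted p = 6.77e-14, and adjusted p = 0.441 with an estimated correlation), Col3a1 by -12.21 ± 0.19. Without the fibroblast-like cells the interferon median was -1.84 (adjusted p = 0.00238, and adjusted p = 0.506 with an estimated correlation) and the median of the genes that rise in senescence was -0.44 (adjusted p = 0.147).

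Each of these counts was the same when adjusted over the list alone. By edgeR's quasi-likelihood test, with a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size, 6650 of 20190 genes changed, 3056 up and 3594 down. Nanog fell in whole libraries but not between EPI-like cells (-0.10, adjusted p = 0.654), and Aen fell by less than 2-fold there (-0.79). Between EPI-like cells alone 3554 of 15586 genes changed (1681 up, 1873 down), 18 of 27 glycolysis and hypoxia genes rose (median 1.26, adjusted p = 5.22e-13, and adjusted p = 0.706 with an estimated correlation), 13 of 19 interferon genes fell and 1 rose (median -2.66, adjusted p = 3.45e-21, and adjusted p = 0.706 with an estimated correlation) and 3 of 17 naive pluripotency genes rose while none fell (median -0.04, with the test pointing up at adjusted p = 0.182). Other medians in this EPI-like comparison were -3.464 for 2-cell-like markers, -0.823 for germ cell-like markers and -0.345 (mean -1.849) for genes that rise in senescence. The last 2 medians were smaller in size than in whole libraries. At the preset correlation the camera call of the germ cell-like markers ended there. The 2-cell-like markers and the genes that rise in senescence were still called lower. With an estimated correlation none of these lists was called. Markers of other classes also differed between these EPI-like cells. Of 16 PrE-like markers 12 rose and none fell (median 2.72, adjusted p = 1.67e-05, and adjusted p = 0.661 with an estimated correlation). At least 10 UMIs over these markers were found in 55.7% of EPI-like cells of control replicate 1, but in 2.92% of those of replicate 2 and 6.08% of those of TBLC, so by this measure only replicate 1 lay above TBLC. Of 18 TE-like markers 10 rose and 3 fell (median 1.39, adjusted p = 0.000809, and adjusted p = 0.661 with an estimated correlation). Of 15 fibroblast markers 14 fell and none rose (median -4.36, adjusted p = 3.82e-23, and adjusted p = 0.485 with an estimated correlation). Without control replicate 1 the whole-library medians were -1.45 for 2-cell-like markers and 0.39 for imprinted genes, and without control replicate 2 that of TE-like markers was 1.04. In the GRCm38 assembly with GENCODE vM21 positions counted from 1, Ttr lies on chromosome 18 from 20665280 to 20674321, Sox17 on chromosome 1 from 4490931 to 4497354, Isg15 on chromosome 4 from 156199424 to 156200818 and Dazl on chromosome 17 from 50279395 to 50293636.

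Between whole libraries of H2O2 and control TBL-blastoids, genes of the primitive endoderm and of its visceral descendants fell. All 16 PrE-like markers fell (median -4.22, camera adjusted p = 1.42e-08, and adjusted p = 0.751 with an estimated correlation). These included Sparc, a matrix protein of the parietal endoderm (-4.67 ± 0.41), and Foxa2, a transcription factor of the endoderm (-5.90 ± 0.16). Of 9 markers of visceral or parietal endoderm 8 fell and none rose (median -3.86, adjusted p = 0.000445, and adjusted p = 0.751 with an estimated correlation), where Ttr was at -8.68 ± 0.22 and the retinol carrier Rbp4 at -6.52 ± 0.17. S100g, a calcium-binding protein, fell by 8.40 ± 0.36 (edgeR quasi-likelihood test, adjusted p = 1.58e-118), from 2636 and 2310 CPM to 7.34 CPM. This p and the SEs rest on a spread pooled over genes and hold no variation between H2O2 libraries. Of 21 lysosome and autophagy genes, which are abundant in visceral endoderm, 14 fell and none rose (median -1.48, adjusted p = 2.41e-05, and adjusted p = 0.635 with an estimated correlation). An example was the protease gene Ctsl (-2.66 ± 0.25), whose exons overlap another gene on its strand. Of 23 matrix and adhesion genes 12 fell and none rose (median -1.14, adjusted p = 0.0161, and adjusted p = 0.635 with an estimated correlation).

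Of the genes that rise in senescence, 6 rose, 7 fell and 9 of 22 did not pass (median 0.18, adjusted p = 0.933), and the cell cycle inhibitor Cdkn1a, a p53 target in both lists, fell by 1.65 ± 0.18 (adjusted p = 2.59e-18). Of 24 S phase genes 12 fell and none rose (median -0.96, adjusted p = 0.000157, and adjusted p = 0.635 with an estimated correlation). These included Mcm5, a subunit of the replicative helicase (-1.40 ± 0.14). Of 38 nuclear genes of oxidative phosphorylation 16 fell and none rose (median -0.90, adjusted p = 2.41e-05, and adjusted p = 0.635 with an estimated correlation), and of 28 spliceosome genes 10 fell and none rose (median -0.90, adjusted p = 0.000164, and adjusted p = 0.635 with an estimated correlation), the splicing factor Srsf2 by -2.51 ± 0.18. Of 27 glycolysis and hypoxia genes 8 rose and none fell (median 0.77, adjusted p = 0.00172, and adjusted p = 0.635 with an estimated correlation). These included Ddit4, an inhibitor of mTORC1 that hypoxia raises (2.99 ± 0.12), and Bnip3, a gene of mitochondrial autophagy (1.93 ± 0.12). The same counts were found when adjusted over the list alone. In all, 10498 of 20190 genes changed, 6261 up and 4237 down. Some of the largest changes lay in genes with long introns or with exons that overlap another gene on the same strand, and whether the counting program caused them was not tested gene by gene. Pde4d (9.10, chromosome 13 from 108449948 to 109953461) and Hs6st3 (8.39) have long introns. Exosc6 (chromosome 8 from 111056339 to 111057664), whose exons overlap another gene's, was at least 2570.7-fold lower with 0 counts in H2O2. Among genes under 20 kb that overlap no other gene, 2379 of 5256 changed. The 5 matrix genes left had a median of -1.14, as with all 23, and the 6 lysosome genes left one of -0.52, and both calls ended (adjusted p = 0.161 and 0.0795).

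**Figure D3:**
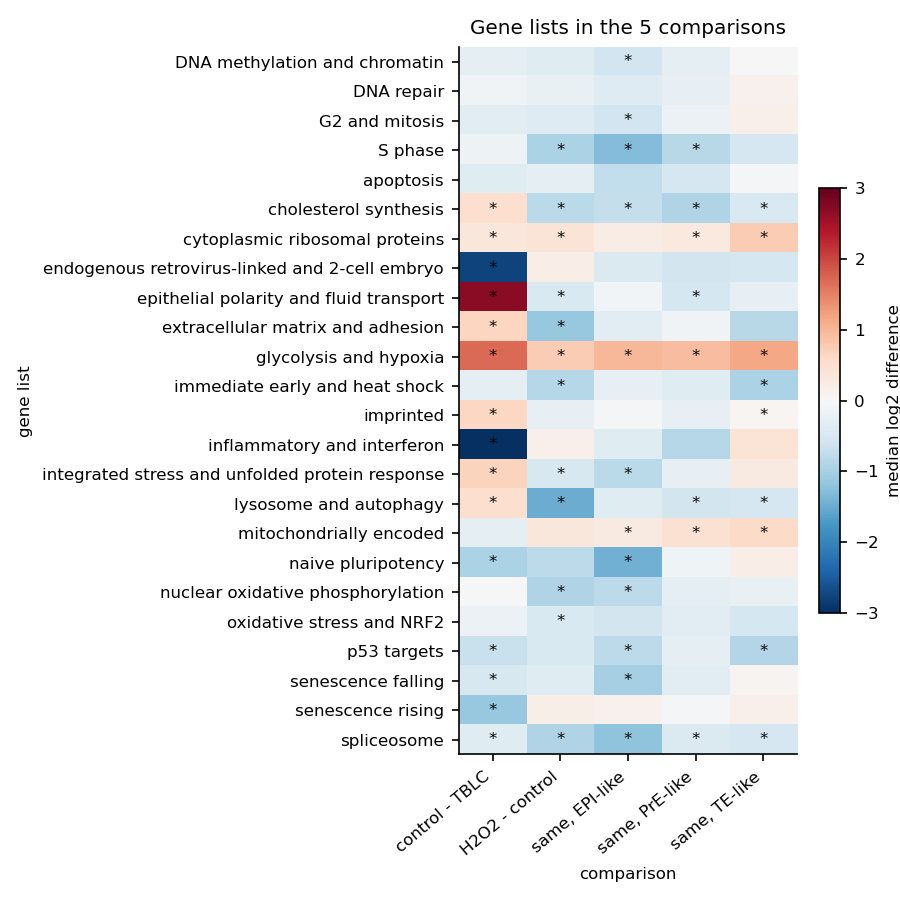
Median log2 difference (colour) of each gene list (vertical axis) in 5 comparisons (horizontal axis), with a star at a camera adjusted p under 0.05 at the preset correlation. S phase genes were at -1.30 in EPI-like cells and at -0.51 in TE-like cells, and glycolysis and hypoxia genes were above 0 in all 5 comparisons, although no starred list had an adjusted p under 0.05 with an estimated correlation.

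In EPI-like cells, which lay in cluster 0 for H2O2 and in clusters 2 and 15 for the controls, genes of naive pluripotency, DNA replication and splicing were lower after H2O2 and hypoxia genes were higher. The H2O2 cluster was named by Nanog, Sox2, Klf2, Esrrb, Fgf4, Dppa5a, Zfp42 and Tfcp2l1, all of them also in the naive pluripotency list. Control cluster 2 was named by 14 markers, Pou5f1 among them. H2O2 and control EPI-like cells lay in separate clusters. The mix of cells in the class and a change within cells therefore cannot be told apart. Of 17 naive pluripotency genes 9 fell and none rose (median -1.45, camera adjusted p = 7.16e-06, and adjusted p = 0.613 with an estimated correlation): Pou5f1 fell by 2.91 ± 0.19 (edgeR quasi-likelihood test, adjusted p = 2.5e-10), from 908 and 869 to 118 CPM, and Zfp42, a marker of the naive state, by 2.48 ± 0.18 (adjusted p = 7.4e-10). Of 24 S phase genes 16 fell and none rose (median -1.30, adjusted p = 6.79e-08, and adjusted p = 0.613 with an estimated correlation). These included Mcm7 (-2.02 ± 0.15) and Pcna, the sliding clamp of replication (-1.74 ± 0.15). Of 28 spliceosome genes 15 fell and none rose (median -1.21, adjusted p = 8.81e-08, and adjusted p = 0.613 with an estimated correlation). An example was Srsf2 (-2.60 ± 0.17). Of 18 genes of DNA methylation and chromatin 6 fell and none rose (median -0.57, adjusted p = 0.00514, and adjusted p = 0.613 with an estimated correlation). These included the de novo methyltransferase Dnmt3b (-2.35 ± 0.15). Of 27 glycolysis and hypoxia genes 13 rose and none fell (median 0.99, adjusted p = 7.16e-06, and adjusted p = 0.613 with an estimated correlation), where Bnip3 was at 2.82 ± 0.12 and the glucose transporter Slc2a1 at 1.61 ± 0.14.

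Stress and senescence genes of EPI-like cells went both ways. Of 25 p53 targets 8 fell, 5 rose and 12 did not pass (median -0.79, adjusted p = 0.0348, and adjusted p = 0.613 with an estimated correlation), where Cdkn1a was at -1.38 ± 0.16 and the stress protein Sesn2 at -2.19 ± 0.14. Of 19 genes that rise in senescence 5 rose and 1 fell, or 4 and 1 when adjusted over the list alone (median 0.12, adjusted p = 0.645), with the vessel growth factor Vegfa at 2.89 ± 0.22. Of 8 genes that fall in senescence 4 fell and none rose (median -0.99, adjusted p = 0.0288, and adjusted p = 0.7 with an estimated correlation). These included Lmnb1, a protein of the nuclear lamina (-1.18 ± 0.13). Of 29 oxidative stress genes 10 fell, 3 rose and 16 did not pass (median -0.56, adjusted p = 0.222), with the superoxide dismutase Sod1 at -2.64 ± 0.19. Of 22 unfolded protein and integrated stress response genes 11 fell and 2 rose (median -0.81, adjusted p = 0.0171, and adjusted p = 0.613 with an estimated correlation). They included the chaperone Hspa5 (-2.65 ± 0.19). PrE-like markers fell as well, 12 of 16 (median -1.76, adjusted p = 0.0132, and adjusted p = 0.945 with an estimated correlation), and their level in EPI-like cells also differed between the controls: 55.7% of EPI-like cells in control replicate 1 and 2.92% in replicate 2 had at least 10 UMIs over these markers, against 0.062% in H2O2. All other counts of these lists were the same when adjusted over the list alone.

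In this class 7940 of 16779 genes changed, 4840 up and 3100 down. Pde4d rose by 8.16 ± 0.18, from 4.19 and 4.53 CPM to 1248 CPM. Across 14724 protein-coding genes, which are not independent replicates, the H2O2 difference went with the ratio of intron to exon length (Spearman's rho 0.407), while the difference between control and TBLC EPI-like cells did not (0.014). Among genes under 20 kb that overlap no other gene, 1688 of 4093 changed, 8 of 12 S phase genes (median -1.33, adjusted p = 0.00025, and adjusted p = 0.714 with an estimated correlation) and 6 of 12 spliceosome genes fell, and 4 of 10 naive pluripotency genes fell at a median of -0.11 (adjusted p = 0.326), so the call of that list ended. Calls of other lists ended there too. Among the lists given above, on fewer genes, the median was -0.67 for 9 unfolded protein and integrated stress response genes (adjusted p = 0.14), -0.45 for 13 p53 targets (adjusted p = 0.298) and -1.07 for 3 PrE-like markers (adjusted p = 0.39). The lists of genes that fall in senescence and of DNA methylation were not tested there.

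**Figure D4:**
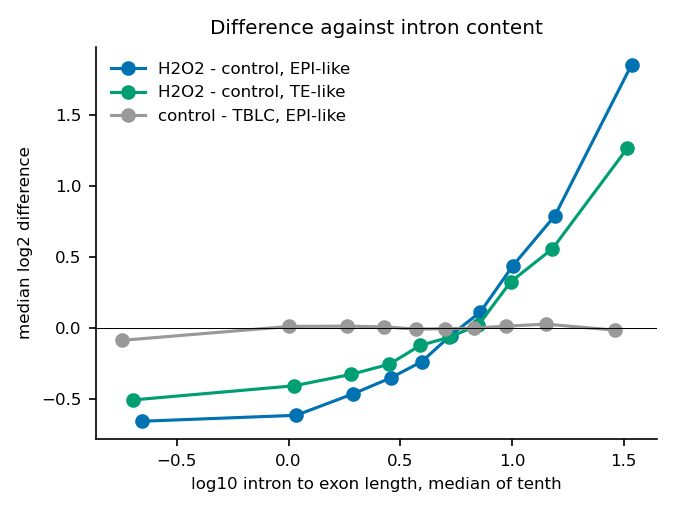
Median log2 difference (vertical axis) of protein-coding genes in 10 bins of the log10 ratio of intron to exon length (horizontal axis), for 3 differences (colours), with 1 point per bin and no error bars. In EPI-like cells the H2O2 minus control median went from -0.65 in the lowest bin to 1.86 in the highest, and the control minus TBLC median was -0.08 and -0.01 in the same bins.

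The 82 PrE-like cells of H2O2 TBL-blastoids, set beside 1781 and 1405 of the controls, had lower levels of most tested markers of visceral or parietal endoderm. These cells were named by raised PrE-like markers, so the presence of the markers is no result, and 32.8% of simulated 2-fold changes were recovered in this class. Ttr and Rbp4 were among the 10 most raised genes of PrE-like cluster 4, which held 630 and 360 control cells and 1 H2O2 cell. The lack of such a subset and lower levels within cells cannot be told apart. Of 16 PrE-like markers 2 rose, 3 fell and 11 did not pass (median -0.01, camera adjusted p = 0.698): Cubn rose from 161 and 215 CPM to 531 CPM (edgeR quasi-likelihood test, adjusted p = 1.48e-11; log2 fold change 0.98 with each library clustered by itself, short of the threshold), while Foxa2 (-1.41 ± 0.18) and Pdgfra, a receptor of the primitive endoderm (-1.22 ± 0.17), fell. Of 8 markers of visceral or parietal endoderm 6 fell and 1 rose (median -2.92, or -1.88 without control replicate 2, adjusted p = 0.00116, and adjusted p = 0.689 with an estimated correlation): Ttr fell by 4.26 ± 0.25, from 476 and 393 to 22.7 CPM, and Rbp4 by 3.17 ± 0.23. Of 27 glycolysis and hypoxia genes 13 rose and none fell (median 0.92, adjusted p = 2.16e-11, and adjusted p = 0.716 with an estimated correlation). An example was the enolase Eno1 (1.91 ± 0.17). Of 24 S phase genes 8 fell and none rose (median -0.83, adjusted p = 5.21e-05, and adjusted p = 0.716 with an estimated correlation), and of 17 cholesterol synthesis genes 8 fell and none rose (median -0.89, adjusted p = 0.000721, and adjusted p = 0.716 with an estimated correlation), where the reductase Dhcr24 was at -2.52 ± 0.21. Cdkn1a fell by 2.30 ± 0.20 (adjusted p = 7.02e-14), and of 19 genes that rise in senescence 4 rose and 5 fell (median -0.05 and mean -0.93, with the test pointing up at adjusted p = 0.893). The counts were the same when adjusted over the list alone. In all 4024 of 14648 genes changed, 1954 up and 2070 down, and 730 of 3623 short genes without overlap did. Among the short genes the cholesterol synthesis list kept 4 genes and a median of -0.88, and its call ended (adjusted p = 0.131). The median over all genes was -0.15, and -0.13 with RLE size factors.

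TE-like cells lay in cluster 3 for H2O2 and in clusters 9 and 11 for the controls. Glycolysis and hypoxia genes rose in them after H2O2, more p53 targets fell than rose, and TE-like markers went both ways. The H2O2 cluster was named by Krt8, Krt18, Krt7, Krt19, Gata3, Gata2 and Hand1, so the presence of these is no result. Of 18 TE-like markers 3 rose, 6 fell and 9 did not pass (median 0.33 and mean -0.38, with the camera test pointing down at adjusted p = 0.409): Krt18 rose by 1.05 ± 0.19 (edgeR quasi-likelihood test, adjusted p = 0.00036), a call that ended at Leiden resolution 0.5 (0.27), with doublets kept (0.91) and with each library clustered by itself (0.84), while Gata2 fell by 3.10 ± 0.17 (adjusted p = 2.53e-08), and Tfap2c, which trophoblast cells need, by 1.14 ± 0.14 (-0.98 among short genes without overlap, short of the threshold). Gcm1, a transcription factor of labyrinth trophoblast, fell by 3.30 ± 0.15. H2O2 and control TE-like cells lay almost wholly in separate clusters, so the mix of cells in the class and a change within cells cannot be told apart. Of 16 PrE-like markers 14 fell and 1 rose (median -1.92, adjusted p = 0.018, and adjusted p = 0.785 with an estimated correlation), beside PrE-like RNA in the controls: 57.9% and 16.5% of control TE-like cells had at least 10 UMIs over these markers, against 3.86% in H2O2. Of 16 EPI-like markers 7 rose and 1 fell (median 0.86, adjusted p = 0.393). Of 27 glycolysis and hypoxia genes 17 rose and none fell (median 1.17, adjusted p = 5.77e-07, and adjusted p = 0.982 with an estimated correlation). These included Pgk1 (1.17 ± 0.18) and Gapdh (1.47 ± 0.23). Of 83 cytoplasmic ribosomal protein genes 24 rose and 1 fell (median 0.76, adjusted p = 1.16e-05, and adjusted p = 0.985 with an estimated correlation). Of 25 p53 targets 11 fell and 2 rose (median -0.89, adjusted p = 0.0132, and adjusted p = 0.982 with an estimated correlation), where Cdkn1a was at -1.78 ± 0.18 and Btg2, a gene that slows division, at -2.12 ± 0.16. Of 23 imprinted genes 8 fell and 4 rose (median 0.07 and mean -0.69, with the test pointing down at adjusted p = 0.0382, and adjusted p = 0.982 with an estimated correlation), H19 by -3.65 ± 0.36 and Peg3 by -2.77 ± 0.22. The median of the imprinted genes turned negative without control replicate 2. Of 8 germ cell-like markers 6 rose and none fell (median 3.34, adjusted p = 0.018, and adjusted p = 0.785 with an estimated correlation). An example was the meiotic gene Sycp3 (4.94 ± 0.23). Without each control in turn the median of the germ cell-like markers was 2.03 and 1.88. Of 24 S phase genes 1 rose, 1 fell and 22 did not pass (median -0.51, adjusted p = 0.26), and of 19 genes that rise in senescence 5 rose and 5 fell (median 0.16 and mean 0.13, with the test pointing down at adjusted p = 0.924). Each of these counts was the same when adjusted over the list alone. In all 7037 of 15728 genes changed, 4072 up and 2965 down, and 1564 of 3765 short genes without overlap did. Calls of several lists ended among the short genes. Among the lists given above, on fewer genes, the median was -0.87 for 13 p53 targets (adjusted p = 0.0702), -2.33 for 3 PrE-like markers (adjusted p = 0.398), 3.67 for 4 germ cell-like markers, all of which rose (adjusted p = 0.277), and -0.29 for 4 imprinted genes (adjusted p = 0.609).

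The H2O2 difference itself differed between the cells named as each class, which lay almost wholly in separate clusters in H2O2 and control. This was tested as an interaction of class and treatment with the library as a block, a test chosen after the data were seen. A gene miscounted alike in every class of a library would drop out of it, but the relation to intron content did not: Spearman's rho was 0.407 in EPI-like, 0.291 in TE-like and 0.28 in PrE-like cells, and -0.135 for the difference between TE-like and EPI-like cells. Between TE-like and EPI-like cells the difference of 3066 of 18170 genes differed by edgeR's quasi-likelihood test, 1482 higher and 1584 lower in TE-like cells. Between PrE-like and EPI-like cells that of 1681 genes did, 615 higher and 1066 lower. In the first contrast cytoplasmic ribosomal protein genes had the smallest camera p, with 4 of 83 higher and none lower (median 0.50, adjusted p = 2.18e-15, and adjusted p = 0.567 with an estimated correlation). After them came nuclear genes of oxidative phosphorylation (5 of 38 higher, none lower, median 0.62, adjusted p = 1.14e-11) and spliceosome genes (4 of 28 higher, none lower, median 0.76, adjusted p = 1.34e-08), each at adjusted p = 0.567 with an estimated correlation. S phase genes (15 of 24 higher, none lower, median 1.18, adjusted p = 3.86e-08) and naive pluripotency genes (11 of 17 higher, none lower, median 1.39, adjusted p = 0.00474) had more members that passed, again at adjusted p = 0.567 with an estimated correlation. Glycolysis and hypoxia genes went both ways, 6 higher and 4 lower of 27 (median 0.17, adjusted p = 0.464). Between PrE-like and EPI-like cells nuclear genes of oxidative phosphorylation had the smallest p (1 of 38 higher, none lower, median 0.44, adjusted p = 4.03e-12, and adjusted p = 0.758 with an estimated correlation). In the same contrast 11 of 16 PrE-like markers were higher and none lower (median 1.61, adjusted p = 6.99e-05, and adjusted p = 0.9 with an estimated correlation), beside the PrE-like RNA seen in control EPI-like cells. The lowest gene of at least 50 CPM in TE-like cells was Cebpa, a transcription factor of the trophoblast and other tissues (-6.06 ± 0.52, adjusted p = 1.39e-06), at 69.8 CPM in control and 0.8 CPM in H2O2 TE-like cells. In EPI-like cells Cebpa stood at 1.1 CPM in the controls and 0.9 CPM in H2O2, so both H2O2 classes lay at similar levels. The chemokine Cxcl12 (-5.61 ± 0.26) went from 138.9 to 2.4 CPM in TE-like cells. Cxcl12 was the most raised gene of control TE-like cluster 9 and among the 10 most raised of unnamed H2O2 cluster 1. For this gene, as for the others in both contrasts, the mix of cells in the class and a change within cells cannot be told apart.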

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

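The tests of the cell filters, of overlapping genes and of EPI-like cells by themselves were chosen after the results were seen, and so was the interaction of class and treatment; the predictions of the other tests were written down before these were run.

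The H2O2 difference differed between TE-like and EPI-like cells for 3066 genes and between PrE-like and EPI-like cells for 1681 genes. The H2O2 difference was more negative in TE-like cells for Cebpa (-6.061), Shisal1 (-5.764), the crosslinking enzyme Tgm2 (-5.649), the chemokine Cxcl12 (-5.608) and Arhgef6 (-4.95). The H2O2 difference was more positive there for the meiotic gene Hormad1 (fitted 8.219, which rests on 0 counts in control TE-like cells; with 3 counts as the floor its fold was at least 13.48 times that in EPI-like cells), the neuronal gene Stmn2 (5.267), the amino acid transporter Slc7a3 (5.084), Zic5 (4.175) and the pluripotency-linked RNA Platr3 (4.071). It was more negative in PrE-like cells for Rnf128 (-4.888), Bhlhe40 (-3.997), the prolactin receptor Prlr (-3.954), Kif21a (-3.441) and Sesn3 (-3.359). It was more positive there for Igfbp1 (4.718), S100g (4.534), the hypoxia gene Ndufa4l2 (fitted 4.342 with 0 counts in control PrE-like cells, and at least 3.06 times by the same floor), Platr3 (3.967) and Slc7a3 (3.822). More positive does not mean higher after H2O2: in PrE-like cells S100g went from 4616.8 to 341.5 CPM, Igfbp1 from 67.3 to 31.6 and Slc7a3 from 5.9 to 4.8, while in EPI-like cells S100g went from 294.1 to 0.8 and Slc7a3 from 221.2 to 12.9. Similar levels in both H2O2 classes can also give such a difference where the control classes differ. In H2O2 TE-like and EPI-like cells Cebpa stood at 0.8 and 0.9 CPM, Shisal1 at 1.0 and 1.1, and Tgm2 at 1.1 and 0.7. Slc7a3 stood there at 11.4 and 12.9 CPM and Zic5 at 24.9 and 24.5. These levels lay further apart for Cxcl12 (2.4 and 6.3 CPM) and Arhgef6 (4.5 and 1.7). The same held for Hormad1 (15.8 and 51.5), Stmn2 (126.2 and 55.4) and Platr3 (7.1 and 16.1). At least 10 UMIs over PrE-like markers were found in 55.7% and 2.92% of control EPI-like cells, against 0.062% in H2O2. Whether the S100g and Igfbp1 values in EPI-like cells follow such PrE-like RNA was not tested. Igfbp1 did not pass with doublets kept or with each library clustered by itself, and Slc7a3 in PrE-like cells did not pass with doublets kept. Among control TE-like cells, Cxcl12 was the most raised gene of cluster 9, and Arhgef6 was among the 10 most raised of cluster 11. H2O2 and control cells of each class lay almost wholly in separate clusters. For both genes, and for the others listed here, the mix of cells in the class and a change within cells cannot be told apart.

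The first pattern is the scarcity of PrE-like cells in the H2O2 library. Clustering or naming may have hidden them, but over the 16 PrE-like markers only 2.735% of H2O2 cells reached 10 UMIs. Of these 131 cells 82 were PrE-like and 41 TE-like. Few cells with such counts thus lay in other clusters. The same markers named the class, so PrE-like cells with low counts of them would be missed by this test too. Poor counting of PrE-like genes could hide them too, but the 50 genes most raised in control PrE-like cells had a median difference of -0.772 (quartiles -1.448 and -0.054) in H2O2 PrE-like cells. The cell filters and the doublet caller together removed 6 H2O2 cells, and counting each as PrE-like gives 1.82%. The H2O2 treatment, a loss of these cells in handling and a difference in how the libraries were made cannot be told apart with 1 H2O2 library.

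The second pattern is the number of genes that differed within a class. Counting of intron reads in the H2O2 matrix alone is consistent with the rho of 0.407 between the EPI-like difference and intron content, against 0.014 for control minus TBLC. Reads shared between overlapping genes may be a second source: of 28 genes at least 16-fold lower in H2O2 in all 3 classes, 22 had exons overlapping another gene on the same strand, 78.6% against 9.8% of 4603 others, a ratio of 8.02 (Fisher's exact test, p = 2.23e-17). With 0 control libraries counted as the H2O2 library was, the treatment and the counting program cannot be told apart. The H2O2 barcodes were also of another length, so a difference in how the libraries were made remains open as well.

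The third pattern is the fall of inflammatory and interferon genes from TBLC to TBL-blastoids. Without fibroblast-like cells the median was -1.837 against -3.032, so the part these cells have and the part other cells have cannot be told apart from this value. In EPI-like cells by themselves the median was -2.659, but fibroblast markers fell there too (median -4.362). Free fibroblast RNA could therefore have reached these cells, but EPI-like TBLC cells held 14.2% of the fibroblast-like level of interferon genes and 1.96% of that of fibroblast markers, a ratio of 7.23, so such RNA is unlikely to be the whole cause.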

How the results depend on the processing

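The comparison of EPI-like control with EPI-like TBLC cells, genes under 20 kb that overlap no other gene, removal of high doublet scores and removal of clusters of low UMI counts were chosen after the data were seen. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Of the alternative counts of changed genes 68 stayed within 1.5 times the main count and 5 did not. Those were 3554 in EPI-like cells only, where fewer genes were tested, and, for genes under 20 kb that overlap no other gene, 2379 in whole libraries, 1688 in EPI-like, 730 in PrE-like and 1564 in TE-like cells, where fewer genes were tested too. Among the 68, DESeq2 called fewer genes than the main test in each comparison it was run on, though within 1.5 times. Without a control replicate no residual degrees of freedom were left, so the counts could not be given a test.

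Shares stayed within their spread under 85 alternatives and moved under 32. At Leiden resolution 0.5 the H2O2 shares were 40.743% EPI-like, 57.389% TE-like and 0% unnamed, and the 2-cell-like clusters held 1.664% of TBLC and 0.099% of control cells. At resolution 2 the H2O2 library was 40.058% EPI-like and 36.945% unnamed, and the controls were 54.95% PrE-like and 6.309% unnamed. With each library clustered by itself the H2O2 library was 32.379% EPI-like, 2.594% PrE-like, 30.282% TE-like, 0.54% 2-cell-like, 0% fibroblast-like and 34.205% unnamed, and TBLC was 0% PrE-like and the controls 0% 2-cell-like. With doublets kept the H2O2 library was 28.272% TE-like and 36.092% unnamed, and the controls 0.554% unnamed. With at least 2000 genes per cell the H2O2 library was 41.967% EPI-like, 19.668% TE-like and 36.446% unnamed. The cause was not tested for any of these.

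The 2-cell-like share in TBLC, control and H2O2 cells was 14.98%, 1.234% and 3.09% at 1 UMI or more, 2.929%, 0.216% and 0.188% at 4 or more, and 31.092%, 1.695% and 1.266% without thinning. Without thinning 33.816% of TBLC fibroblast-like cells reached the count, so that share, like the main one, was not above that of fibroblast-like cells. No share of fibroblast-like cells was taken at 1 or 4 UMIs.

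Of 180 list results, an estimated correlation left 106 on the same side of the threshold and weakened 74, and fry left 109, weakened 68 and strengthened 3. The median of the imprinted list in TE-like cells, 0.07, was 0.158 without control replicate 1 and -0.119 without control replicate 2, and the cause was not tested. Without control replicate 1 the medians of 94 of the 180 lists and the values of 28 of 74 named genes moved by more than the SD of the values without each control. Without control replicate 2 those of 77 lists and 22 genes did, and 1 list median was reversed. These values come from CPM with 0.5 added and not from the fitted model. The interaction called 2952 to 3226 genes between TE-like and EPI-like cells and 1505 to 1904 between PrE-like and EPI-like cells at the other settings. Depth limits PrE-like cells most, since H2O2 had 82 of them.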

Other observations

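Bst2, a membrane protein that holds back budding viruses, was higher in H2O2 than in control TBL-blastoids in whole libraries (log2 fold change 3.58 ± 0.13), in EPI-like cells (2.96 ± 0.12) and in TE-like cells (4.13 ± 0.12). Its level was 604 CPM in the unnamed H2O2 cells and 240 CPM in EPI-like TBLC cells, against 25.6 and 31.7 CPM in control EPI-like cells. Ndufa4l2, a hypoxia gene of the mitochondrion, was higher by 9.31 ± 0.16 in the whole H2O2 library than in the controls. For both genes the H2O2 treatment and the counting program cannot be told apart.

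Control TE-like cells formed 2 clusters. Gata2 stood at 189 CPM in cluster 9 and at 817 CPM in cluster 11, while Cdx2 stood at 56.3 CPM in cluster 9. By the naming rule Cdx2 was a raised marker in cluster 9 but not in cluster 11.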
